A study of Homo sapiens with 8 samples.

How the data were processed

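RNA sequencing was done on AB8 cells, a human cell line derived from podocytes, carrying a doxycycline-inducible construct for human CRB2 with GFP and the S267A change. Per the labels, 4 libraries came from non-induced cells and 4 from cells given doxycycline for 48 h, with replicate numbers 1 to 4 used in both groups. Total RNA was sequenced on a NextSeq 500 as single reads of 75 bases. The submitters' notes list bcl2fastq, Trimmomatic 0.38, HISAT2 2.1.0, HTSeq 0.11.1, DESeq2 1.24.0 and the builds hg38 and GRCh38, without their order. The strand setting of the read counting and the annotation release are not given in the sources used here.

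The authors deposited a table of raw read counts per Ensembl gene, whose values are whole numbers. The second deposited table holds a normalized signal, which is the raw counts divided by 1 factor per library. These factors equalled DESeq2 size factors recomputed from the counts, and fold changes from both tables differed by more than 0.001 for 0 of 26545 genes. Each table holds 58395 genes, of which 58275 matched GENCODE release 29, 57754 matched a current name table and 120 matched neither. At least 1 read fell on 31603 genes. All 748 entries of the 33 gene lists, 736 distinct genes, were found.

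Counts summed to 19668898, 21731488, 21697296 and 16829454 reads in non-induced libraries 1 to 4, and to 19008593, 23081616, 21240294 and 19347540 reads in induced libraries 1 to 4. A gene with 0 counts in a library could have had up to 3, or 0.13 to 0.178 CPM of the library total. This limit covers counting error only.

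Genes were kept by filterByExpr (minimum count 10), which left 15637. Counts were scaled by TMM in edgeR 4.0.16 under R 4.3.3 and compared by the quasi-likelihood test with robust estimation (two-sided, Benjamini-Hochberg FDR 0.05). CPM values use TMM-scaled library totals, and log2 CPM a prior count of 2. Labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples. The design, the gene lists, the alternatives and the naming rule were fixed before the data were examined, and the design has no replicate block.

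Whether the shared numbers pair the libraries was checked from deviations from the group means over 11502 genes with mean log2 CPM above 2. The same-numbered pairs correlated at 0.911, 0.704, 0.707 and 0.648 across genes, and all 8 libraries correlated best with their own number across the groups. Differently numbered libraries correlated at -0.775 to 0.667, and the highest of these lay above the lowest same-numbered value, 0.648. Both libraries numbered 1 lay far from the rest of their groups. With deviations taken from group means, that alone makes the remaining libraries correlate across the groups, paired or not. For the remaining libraries the size of the correlations therefore cannot show pairing, though each correlated best with its own number. The pairing comes from the data and from the shared numbers, and the labels do not say what a number stands for. A fit with the replicate number as a block is therefore given beside the unblocked fit wherever it changed a call.

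Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, lists with 3 or more tested members, adjusted over 32 lists), with an estimated correlation, and with fry. Members past the threshold were counted over all tested genes and adjusted over the list alone. The lists covered Crumbs, Par and Scribble polarity genes, podocyte markers, YAP/TEAD targets, ER chaperones, ATF4 targets, mitochondrial DNA transcripts, respiratory chain subunits, mitochondrial translation, glycolysis, hypoxia, cholesterol synthesis, cell cycle, p53 targets, interferon response, NF-kB and inflammatory genes, extracellular matrix, TGF-beta targets, epithelial junctions, mesenchymal genes, actin and SRF targets, immediate early genes, ERK feedback, heat shock, metallothioneins, Notch, proteasome, lysosome, NRF2 targets, ribosomal proteins, and markers of endothelial, mesangial, parietal or tubular, and immune cells.

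Genes were named by a rule. After CRB2 it took, among genes past the threshold with a mean of at least 1 CPM and groups that did not overlap, the 12 largest rises and the 12 largest falls, leaving out clone-based and pseudogene names. From each list it took up to 4 called members with the smallest p, or up to 2 where none was called, and markers chosen in advance, among them NPHS1, WT1, SYNPO, PODXL, PALS1, PATJ, CCN1, CCN2, ANKRD1, HSPA5, DDIT3 and MKI67. For the block fit the rule was applied after the data were seen, with the same sign in all 4 pairs in place of groups that did not overlap. The rule gave 160 genes, 158 of them tested, and the text names some of these. Values of some withheld genes are not reported here. A gene named outside it is said to be chosen after its values were seen.

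Alternatives were DESeq2 1.42.0, other scalings (RLE, upper quartile, library totals), no filter, a filter at 10 CPM in 4 libraries, no robust estimation, glmTreat against a 1.2-fold change, FDR 0.01, removal of CRB2 or of mitochondrial genes, and each library left out. Block fits with those settings, with each pair left out, and an unblocked fit without both libraries numbered 1 were chosen after seeing the data.

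Both fits were tested on simulated data, 5 sets of 15637 genes with 200 changed genes each. Pair effects and dispersions were taken from the block fit, so same-numbered libraries were paired by construction. The sets therefore cannot show which fit is better if the numbers do not pair the libraries. The unblocked fit recovered 34.6%, 63.6% and 87.6% of genes changed 1.5-, 2- and 4-fold, and 0.322% of its 621 calls were false. The block recovered 73.7%, 91.6% and 96.4%, and 11.2% of its 1038 calls were false, above the 5% aimed at. DESeq2 with the block recovered 67.2%, 82.1% and 95.8%, with 4.32% of 902 calls false. Camera called a list shifted 1.3-fold in 5 of 5 sets and 0 of 155 other lists, in both fits. Beyond the pair effects, genes were simulated independently of each other. These sets therefore cannot show how often camera calls unchanged lists whose members are correlated.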

Results

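RNA was measured in AB8 cells, a podocyte-derived human line, with and without induction of a CRB2 construct carrying the S267A change and GFP. CRB2 is a transmembrane protein of the Crumbs polarity complex. There were 4 non-induced and 4 induced libraries of 16829454 to 23081616 counted reads, with 23636 to 24545 genes detected. The comparison asks which transcripts differ between cells with and without the induced construct. No library from cells given doxycycline without the construct was analysed here, so effects of the drug and of the transgene are not separated. All libraries came from cells with the S267A construct. Effects of the S267A change, of raised CRB2 and of GFP are therefore not separated either.

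CRB2 (ENSG00000148204, GRCh38 chromosome 9, 123356170 to 123380324, plus strand) rose from 20.6 ± 8.47 to 3766 ± 1363 CPM (SD, n = 4 per group). Its read counts were 167, 557, 565 and 364 in non-induced libraries 1 to 4 and 34245, 97191, 96566 and 85310 in induced libraries 1 to 4. The log2 change was 7.51 (SE 0.52, edgeR adjusted p = 0.0016), and 7.53 (SE 0.07, adjusted p = 5.37e-15) with the replicate block. The rise over the same-numbered library was 209-, 164-, 174- and 206-fold. An exact two-sided permutation test gave p = 0.0286, the smallest that 70 labelings allow, and within the 4 pairs, a test chosen after seeing the data, p = 0.125, the smallest that 16 labelings allow. CRB2 took 0.18% to 0.455% of the reads of an induced library. Counts do not tell transgene from endogenous transcripts. In induced library 1 CRB2 stood at 1734 CPM, against 4252 to 4599 CPM in the other 3.

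Without the block, 5 further genes passed the threshold, 4 higher and 1 lower. CEMIP, a hyaluronan-binding protein of hyaluronan breakdown (ENSG00000103888, chromosome 15, 80779343 to 80951776, plus strand), rose 29.6-fold with a log2 change of 4.89 (SE 0.31, adjusted p = 0.0016), from 1.88 ± 0.93 to 55.6 ± 12.3 CPM (SD, n = 4). TRIM55, a muscle RING-finger protein (ENSG00000147573, chromosome 8, 66126896 to 66175487, plus strand), rose by 1.88 in log2 (adjusted p = 0.0145), from 2.86 ± 0.27 to 10.5 ± 2.46 CPM. The long noncoding RNA FBXL19-AS1 (ENSG00000260852, chromosome 16, 30919319 to 30923269, minus strand) rose by 1.43 (adjusted p = 0.0112), from 4.91 ± 0.50 to 13.2 ± 2.04 CPM. C21orf91 (ENSG00000154642, chromosome 21, 17788967 to 17819386, minus strand) rose by 1.12 (adjusted p = 0.0016), from 25.3 ± 2.85 to 55.1 ± 1.62 CPM. THAP11, a zinc-finger transcription factor (ENSG00000168286, chromosome 16, 67842082 to 67844195, plus strand), had a log2 change of -0.90 (adjusted p = 0.0353), from 28.4 ± 0.74 to 15.3 ± 2.29 CPM. All 5 moved the same way in 4 of 4 pairs and passed with the block, where every pair could also be left out.

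THAP11 lies within CENPT on the opposite strand over 2114 bases. CENPT, chosen after its values were seen, stood at 42.8 ± 4.04 CPM without and 88.4 ± 18.1 CPM with induction. CRB2 overlaps DENND1A over 671 bases and C21orf91 overlaps an untested antisense gene, both on the opposite strand. FBXL19-AS1 overlaps FBXL19 on the opposite strand, CEMIP overlaps MESD, and the strand setting of the counting is not given. Whether reads of overlapping genes were counted for the right gene, for the other or left out is therefore not known. Without the block, CRB2, CEMIP and C21orf91 passed with each of the 8 libraries left out. TRIM55 was lost without library 2, 3 or 4 of either group (adjusted p 0.0686 to 0.134), and FBXL19-AS1 without non-induced 2 or 4 or induced 2, 3 or 4 (0.0602 to 0.096). THAP11 was lost without any non-induced library or induced 2, 3 or 4 (0.0628 to 0.219), and at 0.0695 when scaled by library totals.

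**Figure D1:**
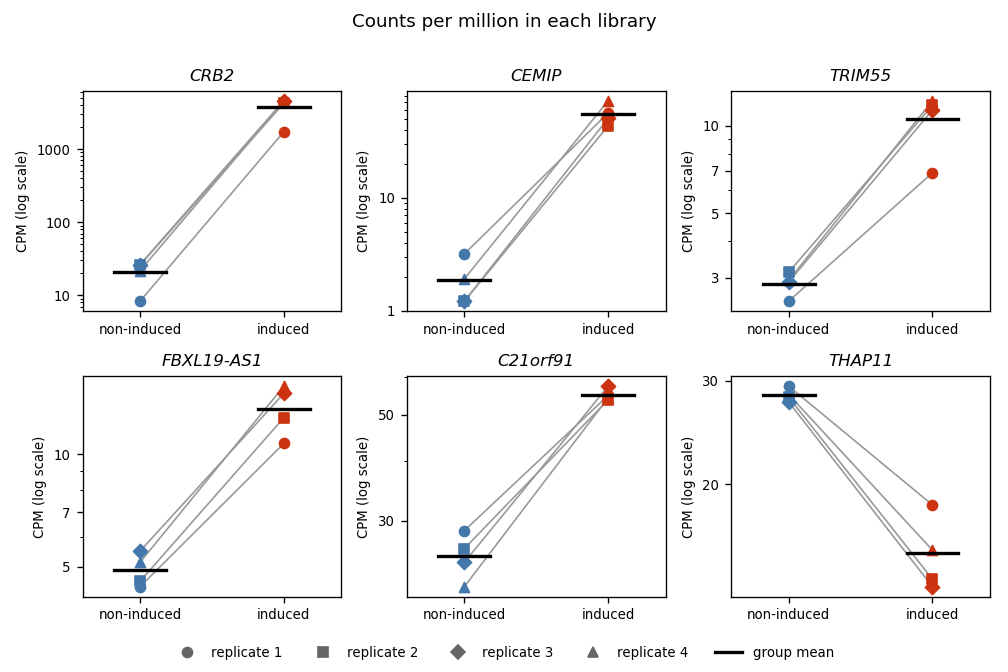
CPM on a log axis for the 6 genes past the threshold without the block, in non-induced (blue) and induced (red) libraries, with lines joining same-numbered libraries and bars at the group means. CRB2, CEMIP, TRIM55, FBXL19-AS1 and C21orf91 were higher and THAP11 was lower in 4 of 4 pairs.

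Over all 15637 tested genes, 6 passed the threshold without the block, 5 higher and 1 lower, and 1466 had an unadjusted p under 0.05. With the block, 2159 passed, 1175 higher and 984 lower, and all 6 were among them. Most of these changes were small, with a median absolute log2 change of 0.24 and 72 genes changed at least 2-fold, 25 up and 47 down. The groups did not overlap for 1101 genes, 7.04% of those tested, where chance gives 2.86% for exchangeable libraries. Both libraries numbered 1 lay far from the rest, so the libraries may not be exchangeable. The block count was 1254 without pair 3, 909 without pair 4 and 1048 with DESeq2, and DESeq2 without the block called 188 genes. More block calls were lower than higher without pair 1 (913 against 808), without pair 4 (482 against 427) and with upper-quartile scaling (1132 against 1076). In simulated data, which were paired by number by construction, 11.2% of block calls were false. Single genes called with the block alone are therefore less certain than CRB2 or CEMIP.

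**Figure D2:**
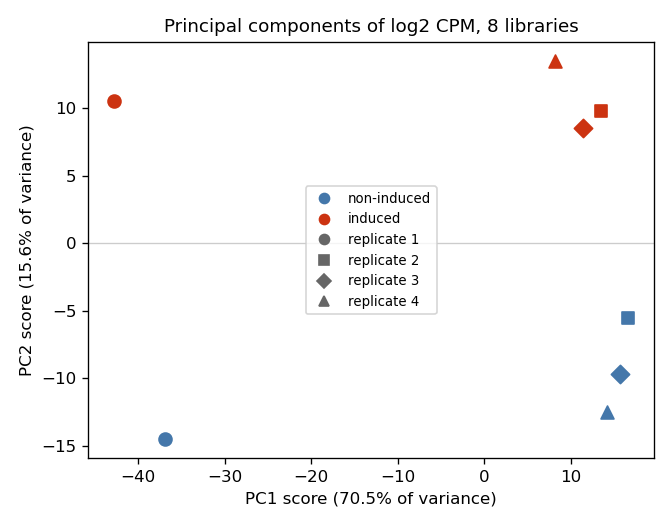
Scores of the 8 libraries on the principal components PC1 and PC2 of log2 CPM, which hold 70.5% and 15.6% of the variance, with color for the group and marker shape for the replicate number. Both libraries numbered 1 lie apart on PC1 (-36.9 and -42.8, others 8.14 to 16.7), and the groups part on PC2 (-14.5 to -5.55 against 8.52 to 13.5).

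With the block, PRKG1, the cGMP-dependent protein kinase I, showed the largest rise among named genes after CRB2 and CEMIP, with a log2 change of 2.45 (SE 0.19, adjusted p = 5.04e-06), from 1.14 ± 0.73 to 6.36 ± 3.20 CPM. TRIM55 and FBXL19-AS1 were also among the 12 largest rises. The others were the protease genes ADAMTS15 (1.62) and MMP13 (1.29), the ectodysplasin receptor EDA2R (1.60), the fibrinogen chain FGB (1.38), ZFHX4-AS1 (1.35), endothelin EDN2 (1.22), the desmosomal plakin PPL (1.18) and LINC02593 (1.13). Several of these were near the limit of detection: ADAMTS15, EDA2R and MMP13 averaged 0.504, 0.640 and 0.715 CPM without induction. MMP13 stood at 0.0934 CPM in non-induced library 2. PRKG1 overlaps CSTF2T and ZFHX4-AS1 overlaps ZFHX4, both on opposite strands. Adjusted p values without the block ran from 0.0016 to 0.802 over these 12 genes. Without pair 1, PPL and LINC02593 no longer passed (adjusted p 0.131 and 0.207, and 0.0572 and 0.107 with DESeq2) and MMP13 did not reach the expression filter, while ADAMTS15 had no adjusted p in DESeq2.

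Among the 12 largest falls with the block, the colony-stimulating factor CSF3 had a log2 change of -2.81 (SE 0.54, adjusted p = 0.0412), the chemokine CCL20 -2.29 and interleukin IL1B -1.34. The tissue plasminogen activator PLAT fell from 42.8 ± 12.1 to 15.5 ± 6.19 CPM (log2 change -1.47, SE 0.15, adjusted p = 0.00478), and its inhibitor SERPINB2 had a log2 change of -1.53. The others were LRRC15 (-1.47), C15orf48 (-1.46), the BCL2 family member BCL2A1 (-1.39), GOLGA7B (-1.36), the serine protease TMPRSS2 (-1.29), LINC02605 (-1.28) and LINC02376 (-1.28). Adjusted p values without the block ran from 0.0878 to 0.706. CSF3 was lost without pair 2, 3 or 4 (0.131, 0.191 and 0.156), CCL20 and IL1B without pair 3 (0.106 and 0.0723) or 4 (0.126 and 0.0731), and TMPRSS2 without pair 4 (0.0575). In induced library 1, CSF3 and IL1B stood at 0.0506 CPM, SERPINB2 and TMPRSS2 at 0.101 CPM and LRRC15 at 0.152 CPM. IL1B was at 0.149 CPM in non-induced library 1. All of these values were near the limit of detection.

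NF-kB targets and inflammatory cytokines were lower in induced cells. With the block 10 of 25 tested members fell and 0 rose, and adjusted over the list alone 14 fell. Without the block 0 passed over all genes, and 18 fell adjusted over the list alone. The list's median log2 change was -0.88. Interleukin IL1A had a log2 change of -1.17 (SE 0.13), from 7.49 ± 2.60 to 3.36 ± 1.61 CPM, and TNFAIP3, an inhibitor of NF-kB signalling, -0.61 (SE 0.06), from 107 ± 29.05 to 70.4 ± 18.2 CPM. The cytokine LIF changed by -0.33 and the subunit gene NFKB2 by -0.39. NFKBIA, the NF-kB inhibitor, had a log2 change of -0.67 and did not pass (adjusted p = 0.0908), though it passed with DESeq2 (0.00378), without robust estimation (0.00145), with the filter at 10 CPM (0.0487) and without pair 1 (3.53e-05). By camera the adjusted p was 2.10e-17 (4.67e-12 with the block), and fry gave 0.0327 (0.069 with the block). With an estimated correlation, camera's adjusted p was 0.292 (0.614 with the block). The count was 18, 10, 9 and 7 without pairs 1 to 4, 7 at FDR 0.01, 19 with DESeq2 and 23 without robust estimation. The leukocyte markers CSF1R and LST1 had log2 changes of -0.65 and -0.58 and did not pass (adjusted p 0.0586 and 0.129), though CSF1R passed with no filter (0.0278) and without pair 1 (0.0266). The other tested marker, CD68, chosen after its values were seen, had a log2 change of 0.19 (adjusted p = 0.722), and camera gave adjusted p = 0.0487 for the leukocyte list, 0.254 with the block and adjusted p = 0.385 with an estimated correlation.

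ER chaperones and degradation genes were higher in induced cells. With the block 12 of 28 rose and 0 fell (adjusted over the list alone 17 rose; without the block 0 over all genes and 7), with a median log2 change of 0.23. SEL1L, a part of the ER-associated degradation complex, rose by 0.42 (SE 0.05), from 103 ± 13.5 to 137 ± 5.53 CPM. The co-chaperone DNAJC3 rose by 0.41, the lectin chaperone CANX by 0.30 and the disulfide isomerase PDIA3 by 0.27. The chaperone CALR rose by 0.42, from 1199 ± 75.4 to 1607 ± 136 CPM, and was lost without pair 4 (adjusted p = 0.108). HSPA5, the main ER Hsp70, had a log2 change of 0.43 and did not pass (adjusted p = 0.116), though it passed with DESeq2 (0.0302), without robust estimation (0.0055) and without pair 1 (3.20e-05). In the list test, camera gave adjusted p = 7.92e-08 for the ER list, and adjusted p = 0.385 with an estimated correlation. Its count was 16, 7, 5 and 5 without pairs 1 to 4 and 4 at FDR 0.01.

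Of 28 ATF4 targets, 10 rose and 1 fell with the block, and 11 rose and 2 fell adjusted over the list alone (0 without the block by either count). They included the cystine transporter SLC7A11 (0.44), the amino acid transporter SLC7A5 (0.30), the pseudokinase TRIB3 (0.29) and the transcription factor DDIT3 (0.46). Camera gave adjusted p = 0.198 without and 0.00219 with the block, and adjusted p = 0.65 with the block and an estimated correlation. Without the block the ATF4 list also passed without non-induced library 1 (0.00126) or induced library 2 or 3 (0.00744 and 0.0141). Among 24 cholesterol synthesis genes, 9 rose and 0 fell with the block, and 9 rose adjusted over the list alone (0 without the block by either count). The sterol desaturase SC5D rose by 0.37 and the transcription factor SREBF2 by 0.25. By camera the adjusted p was 0.00481 for the cholesterol list, and adjusted p = 0.662 with an estimated correlation, and its count was 4 without pair 3 and 4 without pair 4. Its camera call was lost without non-induced library 3 (adjusted p = 0.0817) or induced library 1 (0.0737).

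Of 23 p53 targets, 13 rose and 2 fell with the block, and 15 rose and 2 fell adjusted over the list alone (0 without the block by either count). Besides EDA2R, TP53INP1 rose by 0.68, ZMAT3 by 0.49 and MDM2, the ubiquitin ligase of p53, by 0.40, from 99.1 ± 31.1 to 134 ± 59.3 CPM. In the list test, camera gave adjusted p = 0.00121, and adjusted p = 0.633 with an estimated correlation. The number of p53 targets that rose was 8 without pair 1, 8 without pair 4 and 7 with DESeq2, and the camera call was lost without induced library 1 (adjusted p = 0.0838).

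Glycolysis genes were lower, with 12 of 23 down and 1 up with the block, and 14 down and 1 up adjusted over the list alone (0 without the block by either count). The regulatory kinases PFKFB4 and PFKFB3 had log2 changes of -0.70 and -0.40, the lactate exporter SLC16A3 -0.31 and lactate dehydrogenase LDHA -0.24 (1388 ± 135 to 1174 ± 92.0 CPM). Camera gave adjusted p = 2.93e-04 for glycolysis, and adjusted p = 0.438 with an estimated correlation, and fry gave 0.153 without and 0.04 with the block. Of 19 hypoxia-inducible factor targets, 6 fell and 0 rose with the block, and 9 fell adjusted over the list alone (0 without the block by either count). Carbonic anhydrase CA12 had a log2 change of -0.90, the secreted lipase inhibitor ANGPTL4 -2.41 (lower in 3 of 4 pairs) and STC1 -1.21. By camera the adjusted p was 1.13e-04 for hypoxia, and adjusted p = 0.385 with an estimated correlation. The hypoxia count was 12, 3 and 2 without pairs 1, 2 and 4, and STC1 was lost without pair 4 (adjusted p = 0.0614).

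Ribosomal protein, respiratory chain and proteasome genes were lower by small amounts, with medians of -0.10, -0.07 and -0.07 in log2. With the block 14 of 40 ribosomal protein genes, 6 of 34 respiratory chain genes and 6 of 31 proteasome genes fell and 0 rose, and 27, 6 and 7 fell adjusted over the list alone (0 without the block by either count). RPL11 had a log2 change of -0.15, RPS14 -0.14, the cytochrome oxidase subunit COX4I1 -0.18 and UQCRC1 of complex III -0.17 (SE 0.03 each). In the list test, camera gave adjusted p = 1.05e-07, 1.86e-04 and 0.00121 for the 3 lists, and adjusted p = 0.633, 0.438 and 0.633 with an estimated correlation. Ribosomal counts were 6, 5 and 3 without pairs 2, 3 and 4 and 25 with upper-quartile scaling, respiratory counts were 3 without any pair and 2 with DESeq2, and proteasome counts were 3, 3, 2 and 1 without pairs 1 to 4 and 2 with DESeq2. Camera's proteasome call was lost without induced library 1 (adjusted p = 0.286) or both libraries numbered 1 (0.0641). The medians of respiratory chain and proteasome genes lay within the range of other genes of like length, GC content and expression (-0.079 to -0.005 and -0.074 to 0.001).

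Among Crumbs, Par and Scribble polarity genes, 5 of 25 rose with the block, CRB2 among them, and 0 fell (adjusted over the list alone 7 rose; without the block 1 over all genes and 2). PALS1, the Crumbs adaptor, rose by 0.49 (SE 0.07, adjusted p = 0.00196), from 71.0 ± 6.60 to 100.1 ± 9.61 CPM, and the kinase PRKCZ by 0.37. PATJ, a further Crumbs partner, had a log2 change of 0.09 and did not pass (adjusted p = 0.338). Camera gave adjusted p = 2.35e-04, or 0.0027 without CRB2, and adjusted p = 0.315 with an estimated correlation. Fry gave adjusted p = 0.0327, or 0.137 without CRB2, and 3 genes rose without pair 1, 3 without pair 4 and 3 with upper-quartile scaling.

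Podocyte markers showed 4 of 22 higher and 1 lower with the block, and 6 higher and 1 lower adjusted over the list alone (0 without the block by either count). The protocadherin FAT1 rose by 0.50 (SE 0.05), from 208 ± 28.7 to 296 ± 44.9 CPM, the phospholipase PLCE1 by 0.46 and the junction protein TJP1 by 0.24. The marker that fell was CDKN1C, a cyclin-dependent kinase inhibitor, with a log2 change of -0.30 (lower in 3 of 4 pairs), and it was lost without pair 4 (adjusted p = 0.0733). PODXL rose by 0.49 and was lost without pairs 1, 2 and 4 (adjusted p 0.0874, 0.0864 and 0.155) and with DESeq2 (0.266). WT1 and SYNPO did not pass (log2 changes -0.32 and 0.08, adjusted p 0.211 and 0.63). NPHS1 had 3 reads over all 8 libraries and was not tested. By camera the adjusted p was 0.0468 for podocyte markers, 0.0888 with the block, and adjusted p = 0.578 with an estimated correlation. Without the block it was also lost without non-induced library 1 or 4 (0.399 and 0.0585), without induced library 2 or 4 (0.0687 and 0.116), without both libraries numbered 1 (0.118) and with the filter at 10 CPM (0.132).

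YAP/TEAD targets moved both ways, with 9 of 21 higher and 3 lower with the block, and 11 and 3 adjusted over the list alone (2 and 1 without the block, where 0 passed over all genes). AXL rose by 0.27, CCDC80 by 0.31 and IGFBP3 by 0.59, while GADD45A had a log2 change of -0.30 and tissue factor F3 -0.46. The common reporter genes CCN1, CCN2 and ANKRD1 had log2 changes of 0.04, 0.25 and 0.15 and did not pass (adjusted p 0.698, 0.487 and 0.622). In the list test, camera gave adjusted p = 0.0127 for YAP/TEAD targets, and adjusted p = 0.633 with an estimated correlation, and 5 rose without pair 4. The camera call was lost without non-induced library 1 (0.284) or both libraries numbered 1 (0.0641).

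Of the 32 lists tested, camera called 14 without the block, 14 with it and 12 in both, and fry called 2 without the block and 3 with it. Fry's calls in both fits include the polarity list, which holds the induced CRB2. Without CRB2 that list did not pass fry (adjusted p = 0.137, and 0.105 with the block). Among lists that camera called in at least 1 of the 2 fits, fry gave adjusted p = 0.11 without and 0.0913 with the block for ER chaperones, 0.438 and 0.17 for cholesterol synthesis, 0.381 and 0.069 for p53 targets, and 0.153 and 0.0913 for hypoxia targets. It gave 0.317 and 0.069 for ribosomal proteins, 0.153 and 0.0543 for the respiratory chain, 0.381 and 0.203 for the proteasome, 0.317 and 0.298 for podocyte markers, 0.373 and 0.223 for YAP/TEAD targets, and 0.824 and 0.132 for ATF4 targets. With an estimated correlation, 0 lists were called by camera in either fit, with a smallest adjusted p of 0.292 without and 0.614 with the block. In fry's mixed test, 4 of 32 passed without the block and 29 with it. Across 35 splits of the 8 libraries, 8 gave 14 or more lists, the real one included, so the number of lists does not exclude a chance division.

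**Figure D3:**
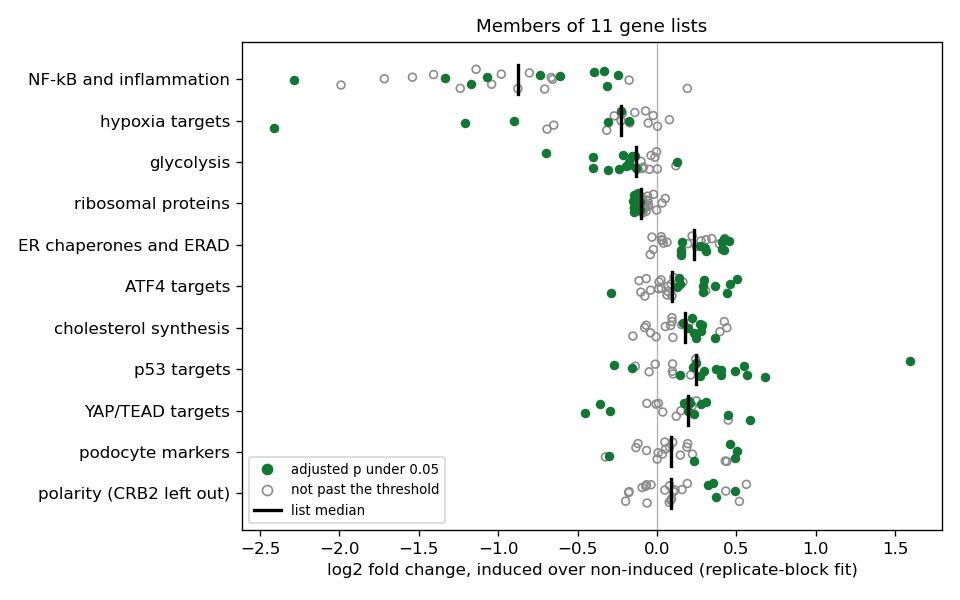
Log2 change, induced over non-induced, with the replicate block for each tested member of 11 gene lists (CRB2 left out), with filled points for adjusted p under 0.05 and bars at the list medians. NF-kB members lie below 0 in 24 of 25 cases and ER chaperone members above 0 in 25 of 28.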

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

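In 44 of 236 groups of 4 libraries, a single library stood far from the other 3, with a gap to the nearest of them that, as a share of the group's range, passed Dixon's 95% critical value. For genes the ratio was taken on log2 CPM, and the values beside it are the same levels as CPM. Chance gives about 1 in 20 such groups. The distant library was a library numbered 1 in 41 cases and another in 3. On PC1 the ratio was 0.955 in non-induced (-36.9 against 14.2 to 16.7) and 0.904 in induced cells (-42.8 against 8.14 to 13.5). The share of reads on mitochondrial DNA stood apart in non-induced library 4 (0.863), at 3.91% against 3.09% to 3.20%.

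Library 1 was lowest for CRB2 in both groups, at 8.31 CPM against 21.8 to 26.4 in non-induced (0.834) and 1734 CPM against 4252 to 4599 in induced cells (0.92). ACTB was also lower in libraries numbered 1. It stood at 3697 CPM against 5885 to 6211 (0.896) and at 3223 against 5279 to 5372 when induced (0.966). Other lower values were those of VCAN (0.892 non-induced, 0.884 induced), ADAM12 (0.916, 0.864) and LRRC15 (0.874, 0.936) in both groups. The gap passed in the non-induced group alone, with library 1 lower, for TPM1 (0.991), COL4A1 (0.981), SLC16A3 (0.922), CA12 (0.918), F3 (0.862), WT1 (0.878), CCN1 (0.933) and LINC02376 (0.8293), and in the induced group alone for TRIM55 (0.872), CSF3 (0.835), C15orf48 (0.925), AXL (0.857), CCDC80 (0.88) and CCN2 (0.864).

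MDM2 and DDIT3 were higher in libraries numbered 1. MDM2 stood at 146 CPM against 80.9 to 85.9 (0.899) and at 223 against 103 to 107 when induced (0.946), and DDIT3 at 34.2 CPM against 10.2 to 11.7 (0.887) and 40.8 against 15.01 to 16.97 (0.877). JUNB (0.919, 0.982) and UQCRC1 (0.909, 0.915) were also higher in both groups. With library 1 higher, the gap passed in the non-induced group alone for HSPA5 (0.888, 1565 CPM against 681 to 747), PRKG1 (0.945), EDA2R (0.833) and TP53INP1 (0.843), and in the induced group alone for SLC7A11 (0.868), HSPA4L (0.906) and PRKCZ (0.921). Of the other libraries, induced library 4 was higher for EDN2 (0.884, 6.93 CPM against 3.29 to 3.59), and non-induced library 2 was lower for CCL20 (0.914, 10.3 CPM against 12.4 to 12.6).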

How the results depend on the processing

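Without the replicate block, CRB2's log2 change stayed at 7.25 to 7.75 under every alternative run. The counts of 6 genes past the threshold, 5 higher, 1 lower and 5 changed at least 2-fold became 188, 80, 108 and 32 with DESeq2, 37, 16, 21 and 10 with no filter, and 3, 3, 0 and 3 at FDR 0.01. The lower count was 2 with the filter at 10 CPM and 0 with glmTreat. With single libraries left out, the 4 counts ran from 3 to 16, 3 to 9, 0 to 7 and 3 to 10, and without both libraries numbered 1, chosen after seeing the data, they were 543, 242, 301 and 40. With the replicate block they were 2159, 1175, 984 and 72. The block changed no call other than these, the member counts and the lists named in the report or among the other observations. In the block fit, whose alternatives were chosen after seeing the data, DESeq2 gave 1048, 545 and 503 and shared 985 of the 2159 genes, and FDR 0.01 gave 895, 485, 410 and 39. At least 2-fold changes numbered 138 with no filter and 14 with the filter at 10 CPM. With single pairs left out, the 4 block counts ran from 909 to 1969, 427 to 1118, 482 to 913 and 38 to 86. Other scalings gave 2150 (RLE), 2208 (upper quartile) and 2199 (library totals) with the block, and 48.7% to 57.4% of calls were higher against 54.4%. The 14 lists called by camera became 0 with an estimated correlation, 2 with fry and 4 with fry's mixed test. The polarity list, which holds CRB2, was among the lists called by fry and by its mixed test. No named gene and no tested list that was called reversed its direction under the alternatives run. The balance of higher to lower calls did turn: more genes were lower without the block with DESeq2, with no filter and without both libraries numbered 1 (counts above), and with the block with upper-quartile scaling (1076 higher, 1132 lower), without pair 1 (808 and 913) and without pair 4 (427 and 482). Of 130 named genes past the threshold with the block, 87 stayed past it with every pair left out in turn, and 86 of these also with DESeq2. Many of them were named for a small p or a large change in that fit, so their share does not stand for all calls. Of all 2159 block calls, 1459, 1641, 1188 and 881 were also called without pairs 1 to 4. Fewer genes or libraries tested, or a stricter threshold, are part of some of these settings, and the cause was not tested for the others. Data simulated with the same number of libraries had pairing by number built in. There the unblocked fit recovered 34.6% of 1.5-fold changes and the block 73.7%.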

Other observations

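Extracellular matrix genes moved in both directions: with the block 8 of 27 rose and 9 fell, and 9 and 12 adjusted over the list alone. Fibronectin FN1 had a log2 change of -0.40 (SE 0.03), from 4070 ± 652 to 3079 ± 429 CPM, the membrane protease MMP14 -0.32 and TGFBI -0.27, while the proteoglycan VCAN rose by 0.32 and the basement membrane collagen COL4A1 by 0.27. Of 17 TGF-beta targets 1 rose and 4 fell (1 and 5 adjusted over the list alone), with ADAM12 at -0.32. The plasminogen activator PLAU and the laminin chain LAMB3, chosen after their values were seen, had log2 changes of -1.04 and -0.74 (block adjusted p = 0.0159 and 0.011). Of 17 epithelial junction genes 1 rose and 6 fell (3 and 6 adjusted over the list alone), namely CLDN4 (-0.63), CLDN1 (-0.44) and JUP (-0.30) among those lower and DSP (0.23) higher. Of 14 mesenchymal genes 0 rose and 2 fell by either count, with the transcription factor SNAI2 at -0.33, from 21.5 ± 0.93 to 17.1 ± 2.26 CPM, and CD44 at -0.44. Of 21 actin and SRF targets 1 rose and 3 fell by either count, TPM1 at 0.25 and ACTB at -0.19 among them. Camera gave adjusted p = 0.388 for matrix, 0.311 for TGF-beta, 0.663 for junctions and 0.586 for actin. For mesenchymal genes it gave 0.0544 without and 0.00658 with the block (adjusted p = 0.614 with the block and an estimated correlation), and fry gave 0.317 and 0.0302. Without the block camera also called mesenchymal genes without non-induced library 1 (0.0122), induced library 2 or 3 (0.0393 and 0.0417) or both libraries numbered 1 (0.0141), and with library totals (0.0499), and it called matrix (0.00527), TGF-beta (0.0116) and actin genes (0.00527) without non-induced library 1. Without the block 0 members of these 5 lists passed by either count. Matrix genes that rose numbered 5 without pair 3 and 4 without pair 4, junction genes that fell 3 without pair 3 and 3 without pair 4, actin genes that fell 5 without pair 1 and 1 without pair 3, and mesenchymal genes that fell 1 without pair 4, where CD44 was lost (adjusted p = 0.0835).

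Of 15 ERK feedback genes 1 rose and 7 fell with the block, and 1 and 8 adjusted over the list alone (1 and 1 without the block). PHLDA1 had a log2 change of -0.41 and the transcription factor ETV4 -0.47, while the receptor EPHA4 rose by 0.71. Camera gave adjusted p = 0.0363, and adjusted p = 0.633 with an estimated correlation, and 11 fell without pair 1 and 3 without pair 4. The call was lost without non-induced library 2 or 3 (0.136 and 0.175) or induced library 4 (0.196), and fry gave 0.381 without and 0.17 with the block. Of 21 immediate early genes 3 rose and 5 fell (3 and 7 adjusted over the list alone, 0 and 1 without the block), with KLF4 at 0.53, JUNB at -0.42 and KLF6 at -0.28. Their mean log2 change was 0.03 and their median -0.09, with camera's direction down (adjusted p = 0.198), and 9 fell without pair 1, 3 without pair 3, 2 without pair 4 and 3 with DESeq2. Camera called them without non-induced library 4 (0.0462), induced library 1 (0.00398) or both libraries numbered 1 (0.0271), and with the filter at 10 CPM (0.0219).

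Few members changed with the block in the other lists. Cell cycle genes had 2 of 30 higher and 2 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.908), with AURKB at -0.23 and MKI67 at 0.13, and MKI67 was lost without pairs 2, 3 and 4 (0.0893, 0.0639 and 0.121). The higher count was 0 without pair 3 or 4, and the lower count was 1 without pair 4. Interferon genes had 1 of 25 higher by either count, IFIH1 at 0.41 (camera 0.374, 0.0503 with the block and 0.0266 without induced library 4), and heat shock genes 1 of 17 by either count, HSPA4L at 0.41 (camera 0.437). Interferon genes that rose numbered 2 without pair 1, 3 without pair 2 and 3 without robust estimation. NRF2 targets had 2 of 16 higher and 4 lower (2 and 5 over the list alone; camera 0.71), with HMOX1 at -0.42, and 2 and 1 lower without pairs 3 and 4. Lysosome genes had 2 of 21 higher and 1 lower by either count (camera 0.858), and none of these 3 passed with each pair left out in turn. Metallothionein genes had 1 of 6 higher and 1 lower (1 and 2 over the list alone; camera 0.374), and mitochondrial translation 1 of 30 higher (0 over the list alone; camera 0.254). The metallothionein rise was lost without pair 1 or 2 and the fall without pair 3 or 4. The mitochondrial translation rise was lost without pair 2 or 4. For the 13 transcripts of mitochondrial DNA and 12 Notch genes, edgeR called 0 by either count with the block (camera 0.678 and 0.437), 5 of each had an unadjusted p under 0.05, and DESeq2 with the block called 0 and 1. Without pair 2, 5 mitochondrial transcripts fell, and without pair 1, 2 Notch genes rose and 1 fell. The Notch ligand JAG1 had a log2 change of 0.92 and adjusted p = 0.0602, and it passed with DESeq2 (0.0013), without robust estimation (0.000785), with library totals (0.0442), upper-quartile scaling (0.0454) or the filter at 10 CPM (0.0268), and without pair 1 (0.00939) or 4 (0.0234).

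Markers of other cell types were mostly too low to test. Of the parietal and tubular markers tested, PAX8 was well expressed, at 458 CPM without and 361 CPM with induction. HAVCR1 averaged 19.8 and 25.7 CPM. Endothelial VWF and TIE1, the only 2 of 11 tested, did not pass (log2 changes 0.56 and -0.32). Of 5 mesangial markers 1 rose by either count (PDGFRB, 0.34), with a negative median (-0.03), a positive mean (0.04) and camera's direction up (adjusted p = 0.466). Of 3 parietal and tubular markers PAX2 rose (0.36) and PAX8 had a log2 change of -0.35 (2 higher and 1 lower over the list alone; 1 and 1 without the block; camera 0.63). PDGFRB was lost without pairs 1, 3 and 4 (0.119, 0.104 and 0.161) and PAX8 without pairs 3 and 4 (0.0622 and 0.197). Of 3 immune markers 0 passed over all genes and 2 fell adjusted over the list alone (1 without the block), with camera adjusted p = 0.0487 without and 0.254 with the block, and adjusted p = 0.385 with an estimated correlation, fry 0.11 and 0.203, and the camera call was also lost with library totals (0.0545) and without non-induced 2 or 3 or induced 1, 3 or 4 (0.0506 to 0.124).

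The tests against doxycycline, the pair numbered 1 and leukocytes below were chosen after the results were seen. The 6 genes called without the block were set against other divisions of the libraries: 1 of 35 splits, the real one, gave as many genes, and the highest of the others gave 1, which excludes a chance division only if the libraries are exchangeable. That is in doubt, since both libraries numbered 1 lay far from the rest and each library correlated best with its own number. The 8 splits that part all 4 pairs are too few for a share under 0.05. Among these the real one gave 6 genes without and 2159 with the block, and the highest other 0 in both fits. For the 14 lists called by camera, 8 of 35 splits gave as many and the highest other gave 19, so chance is not excluded. The 7 others with 14 or more all keep both libraries numbered 1 on the same side, which points to a structure of the samples, and the highest among the 7 other splits parting all 4 pairs was 10.

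CEMIP, TRIM55, FBXL19-AS1, C21orf91 and THAP11 changed with induction. Reads shared with the CRB2 sequence do not account for this, since 0 of the 5 genes share a 31-base word with a CRB2 transcript on either strand; GFP and vector sequence were not searched. A response to CRB2 S267A and a response to doxycycline rather than the transgene cannot be told apart, since 0 libraries were given doxycycline without the construct. For THAP11, the sum with CENPT, on the opposite strand, was 71.1 ± 3.52 CPM without and 103.7 ± 16.4 CPM with induction.

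Of 25 NF-kB and inflammatory genes 10 fell with the block and 0 passed without it over all genes. Camera gave adjusted p = 2.10e-17, and 0.292 with an estimated correlation (0.614 with the block), and fry gave 0.069 with the block. The pair numbered 1 alone does not account for the falls, since 18 members fell without it. Fewer leukocytes in the induced cultures do not account for it either: of the 4 abundant leukocyte transcripts tested, CD14 averaged 0.379 CPM in the non-induced libraries, LYZ 0.0358, PTPRC 0.0127 and TYROBP 0, while CSF1R and LST1, also on the immune list, averaged 1.86 and 1.16 CPM without and 1.19 and 0.771 CPM with induction and CD68 0.604 and 0.683 CPM, and none of the 3 passed. Doxycycline itself stays open and cannot be told apart from the transgene, since 0 libraries were given doxycycline without the construct. A lower NF-kB activity in cells expressing CRB2 S267A is 1 hypothesis that remains, untested here, since NF-kB activity itself was not measured. These libraries could not tie it to the S267A change rather than to raised CRB2 or GFP.

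With the block 14 of 40 ribosomal protein, 6 of 34 respiratory chain and 6 of 31 proteasome genes fell by small amounts, 0 passed without it, and the list calls were lost with an estimated correlation (adjusted p = 0.633, 0.438 and 0.633); respiratory chain genes that fell numbered 3 without each pair in turn. Each list's median was set against 10000 random lists of genes matched on length, GC content and expression. The ribosomal median (-0.10) lay at percentile 0.28 of matched lists, whose own median was -0.066 (-0.092 to -0.037), so such a trend may account for part of the change. Matched genes were drawn independently and do not carry the correlation among ribosomal genes. The percentile therefore cannot decide whether the trend accounts for all of the change. The respiratory chain (-0.07, percentile 10.6) and proteasome (-0.07, percentile 3.72) medians lay within the middle 95% of matched lists, so such a trend may account for both. A biological explanation stays open for the ribosomal change, as does doxycycline, which was not tested.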
